A study of Shewanella oneidensis with 8 samples.

How the data were processed

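RNA from the electrode-associated cells of 8 flow-cell cultures, 4 of the wild type and 4 of the SO_3096 mutant, was measured on 1-colour (Cy3) Agilent arrays. Per the labels' protocols, cells were given about 1 h to attach, medium then flowed for 48 h, total RNA was extracted with Trizol, and 25 ng was labelled. The labels call the replicates biological, and whether a run of the flow cell was shared between strains was not given in the sources used here. The 8 arrays lay on 1 slide and came from 1 scan, so no block for slide or scan was fitted. Wild-type arrays filled 1 row of the slide and mutant arrays the other.

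Spot intensity values were made by Agilent Feature Extraction 11.5.1.1, per the file headers, as processed signals that are background-subtracted and detrended within each array and not normalized between arrays. The submitters' processing notes name Feature Extraction 8.1 and limma 3.36.2, without saying what each did. The series matrix holds log2 values deposited by the authors. Judged from the values, these were quantile-normalized over all spots, since the sorted columns differ by at most 0.35, and genes were not centred. Their column medians lie between 8.704 and 8.7084, and each column correlates across spots at r of 0.9876 to 0.9929 with the log2 processed signal of its array. The background step behind them was not given in the sources used here.

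For the main values, the log2 processed signal of each array was reduced by its 75th percentile over the 13379 non-control probes. The 536 control spots were left out, as were spots marked as outliers by the scanner software, which numbered between 0 and 3 per array. No probe was saturated. A probe was kept if it was well above background on at least 3 arrays of at least 1 strain, which kept 13277 probes and left out 102. The value of a gene was the mean of its kept probes. Of 4769 locus tags, 4186 had 3 probes, 238 had 2 and 345 had 1, and 4736 were tested, 4576 on the chromosome and 160 on the megaplasmid. A probe that was not well above background on any array of a strain has only a bound there. The bound sets the mean of the brighter strain against the dimmer strain's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. A gene has only a bound where this holds for all its probes, and no fold is given where the bound is under 1. The dimmer arrays of the mutant limit what can be seen of weak genes there.

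Genes were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3, data.table at version 1.17.8) on strain means without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each fit had 6 residual degrees of freedom and 5.43 from the prior. Folds are of mutant over wild type, and SE is limma's moderated standard error of the log2 fold. Tags were matched to the gene list of assembly ASM14616v2, used for symbols and for the order of genes and not for coordinates. Of the tested tags, 4135 matched and 1219 had a symbol, and other genes are named by tag.

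Gene lists were fixed before the data were examined. For lists defined by the wording of gene products, symbol patterns were used in its place because that source pairs tags with symbols and not with products. This was decided before any test and covers heme synthesis, ribosomal proteins, aminoacyl-tRNA ligases, flagella, chemotaxis, cyclic di-GMP and transposases. Lists were tested with camera from limma at a preset correlation of 0.01, two-sided, and adjusted over the 26 lists with at least 4 tested members. Chemotaxis and cyclic di-GMP had 2 tested members each and transposases 0, so they were not tested as lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. Runs of at least 4 neighbouring tested genes called in the same direction were counted against 10000 permutations of the calls, which treat genes as exchangeable.

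The genes named in the text follow a rule fixed before the data were examined. It takes SO_3096, then the 12 highest and 12 lowest log2 folds among called genes whose 4 mutant values all lie to one side of the 4 wild-type values. It adds all tested members of the lists of cytochrome c maturation, extracellular electron transfer and neighbours of SO_3096. From every other list it takes up to 3 called members with the largest change, or the member with the smallest p where none was called. It also takes the first, the last and the most changed gene of the 8 longest runs. Genes outside this rule were chosen after their values were seen. Some are said to be so, and others stand beside named genes as members of the same list, run or segment.

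Alternatives were quantile normalization, median centring, other filters on dim probes, outlier spots kept, the brightest probe of each gene, the series matrix values, the replicate number as a block, trend and robust variances, array weights and leaving out each array in turn. Stricter thresholds and shorter runs were also tried. After the data were seen, normexp on median signals with an offset of 50 (alone and with quantile normalization), cyclic loess, and a fit without the dimmest mutant and the brightest wild-type array were added. The fit was tested on simulated data of 4736 genes for this comparison with 200 changed. It recovered 28.8% of genes changed by a log2 fold of 0.5, 86.6% at 1 and 100% at 2, with 5.67% false among the calls. All 5 planted runs of 6 genes were found, a shifted list of 30 genes was called, and 0 of 20 unchanged lists were. Simulated genes varied independently of each other, so this cannot show how often camera calls unchanged lists of correlated genes. Dimness entered the simulation only as a constant per array, which the percentile scaling takes out, and no background floor was simulated. The false share therefore does not cover effects of the dimmer mutant arrays on weak genes. In the real data the estimated correlation was 0.868 for the ATP synthase list.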

Results

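Transcript levels were measured in Shewanella oneidensis MR-1, a bacterium that respires on solid electron acceptors such as electrodes. The cells were taken from the working electrode of an electrochemical flow cell after 48 h of lactate medium flowing at 5.5 mm per min, with the electrode held at 0.2 V against the standard hydrogen electrode. The wild type, 4 biological replicates per the labels, was compared with a strain lacking SO_3096, also 4 replicates. SO_3096 codes for a sigma factor of the extracytoplasmic function (ECF) family, the class of RNA polymerase subunits that often answer to stress at the cell envelope. Both strains carried the same expressed construct, AFP in the labels. The series title ties SO_3096 to the formation of electroactive biofilm, and the comparison asks which transcripts differ between the strains on the electrode.

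Each sample was hybridised in 1 colour to an array with 13379 probes for 4769 locus tags, most of them covered by 3 probes, and 4736 genes were tested. The mutant arrays were dimmer. The 75th percentile of the signal was 1976, 1338, 1752 and 1216 on wild-type arrays 1 to 4 and 1215, 389.6, 645.6 and 662.8 on mutant arrays 1 to 4. The median signal of the E1A spike-in controls overlapped between the strains, at 213.5, 193.8, 185 and 152.2 on wild-type arrays and 208.5, 136.5, 214 and 177.7 on mutant arrays. Probes well above background made up between 98.82% and 99.74% of all probes in the wild type and between 95.43% and 98.7% in the mutant. Gene values of 2 arrays correlated across genes at r of 0.98 to 0.989 within the wild type, 0.969 to 0.98 within the mutant and 0.887 to 0.936 between the strains. All wild-type arrays lay in 1 row of the slide and all mutant arrays in the other, so slide row and strain cannot be told apart. The number of arrays limits the precision of every value.

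The deleted gene was low on every mutant array, and so were its neighbours SO_3097 and SO_3098. Of the 3 probes of SO_3096, 2 were not well above background on any mutant array. Their wild-type signal was at least 831-fold and at least 2060-fold higher. The remaining probe was 31.7-fold lower in the mutant, at -2.68 ± 0.25 against 2.31 ± 0.35 (SD, n = 4 each) on the log2 scale relative to each array's 75th percentile, and stayed well above background on all 4 mutant arrays. Where the probes lie relative to the deleted part was not given in the sources used here. limma gave SO_3096 an adjusted p of 4.36e-12. SO_3097, the next tag, fell 29.3-fold (log2 fold -4.87, SE 0.12, limma adjusted p = 6.09e-11), and SO_3098 fell 26.5-fold (log2 fold -4.73, SE 0.28, limma adjusted p = 2.44e-07). SO_3100 was also lower, with a log2 fold of -0.95, although normexp at the same percentile left it at -0.11 and ended the call. The run of 5 neighbours from SO_3090 to SO_3094 was higher in the mutant, with log2 folds from 0.69 to 0.95, although the SO_3094 call was lost without mutant replicate 3 (limma adjusted p = 0.0535). Of the 12 neighbours within 6 tags of the deleted gene, 5 were higher, 3 lower and 4 did not pass the test. Adjusted over the list alone, 6 were higher and 3 lower. SO_3102 had a log2 fold of 0.48 (limma adjusted p = 0.0546). It was called higher with both normexp settings (0.00418 and 0.0296), the series matrix values (0.0261) and trend and robust variances (0.0488), and without mutant replicate 4 (0.0348). The SO_3091 call was lost without mutant replicate 2 and wild-type replicate 1 together (limma adjusted p = 0.0505). The median log2 fold of the list was 0.36, while camera and fry gave it the direction down, and it passed limma's fry (adjusted p = 0.000186) but not camera.

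A small set of genes was lowered far more than any gene was raised. SO_1381 stood at 4.27 ± 0.32 in the wild type and -6.23 ± 0.18 in the mutant (SD, n = 4 each), where 2 of its 3 probes were not well above background on any array, so its fold is not given. SO_1773 fell 150-fold (log2 fold -7.23, SE 0.16, limma adjusted p = 3.57e-11) and SO_2008 fell 119-fold (log2 fold -6.90, SE 0.18, limma adjusted p = 7.29e-11). SO_2008 lay in a run of 6 lowered genes, SO_2007 to SO_2012, with a median log2 fold of -5.26. Among genes whose 4 mutant values all lay above the wild type, the largest rises were those of SO_3062, 5.6-fold (log2 fold 2.49, SE 0.17, limma adjusted p = 8.98e-07), of the megaplasmid gene SO_A0109, 5.13-fold, of SO_1977, 5.03-fold, and of SO_4476, 4.37-fold. Next came ohr (SO_0976), for resistance to organic hydroperoxides, at 4.13-fold, and SO_A0108, the neighbour of SO_A0109, at 4.1-fold. SO_4740, named after its values were seen, rose 4.01-fold with values of the strains that overlapped. SO_3910 and SO_3909 rose 3.94-fold and 3.53-fold. cysD (SO_3727), a subunit of the enzyme that activates sulfate, rose 3.77-fold. SO_1258 rose by a log2 fold of 1.75 and SO_1689 by 1.73.

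**Figure D1:**
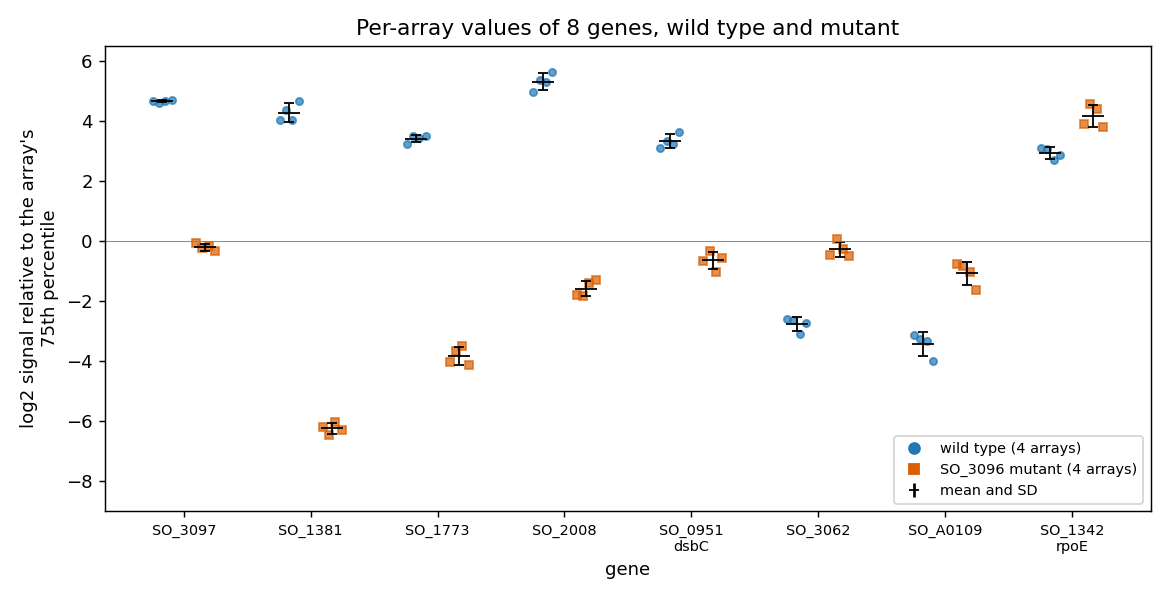
Log2 signal relative to each array's 75th percentile for named genes, with 1 point per array, 4 arrays per strain, and black bars for the mean and SD. The 4 mutant values lie below all 4 wild-type values for SO_3097, SO_1381, SO_1773, SO_2008 and dsbC (SO_0951), and above them for SO_3062, SO_A0109 and rpoE (SO_1342).

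Over all genes, 1115 of 4736 changed between the strains at a limma adjusted p under 0.05, 799 higher and 316 lower in the mutant. Of these, 300 changed at least 2-fold, 180 higher and 120 lower. The 4 values of 1 strain lay wholly above or below those of the other in 954 of the changed genes and in 26.4% of all genes, where chance gives 2.86%. Higher genes made up 71.7% of the calls, a share that other scalings moved. It was 85.9% (1722 higher, 282 lower) with normexp at the same percentile, 60.3% (643 and 424) with the authors' series matrix values and 53.2% (575 and 505) with cyclic loess. The count fell to 719 without wild-type replicate 3, 742 without wild-type replicate 4 and 694 without mutant replicate 3.

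On the megaplasmid, the large plasmid of this strain, a segment of genes was low in the mutant. All 19 tested genes from SO_A0001 to SO_A0019 were called lower, the longest run of the comparison, and so were SO_A0171 to SO_A0174. None of the 51 probes of SO_A0001 to SO_A0015 and SO_A0171 to SO_A0174 was well above background on any mutant array, while all 51 were on all 4 wild-type arrays. The filter had already required at least 3 wild-type arrays of such probes. In the reference order, the 16 of these 19 genes that could be placed lay side by side, with 0 other tested genes between them. Wild-type signal was at least 235-fold higher for SO_A0004, at least 104-fold for SO_A0005, at least 91.4-fold for SO_A0001, at least 89.7-fold for SO_A0003 and at least 58.9-fold for SO_A0006. The bound was 38.1-fold for SO_A0013, 33.1-fold for SO_A0014 and 34.1-fold for SO_A0173. No fold is given for SO_A0009, whose bound fell under 1. SO_A0016 to SO_A0019 were lower but remained above background, and SO_A0019 fell 11.8-fold (log2 fold -3.56, SE 0.18, limma adjusted p = 3.99e-08). Of the other 137 megaplasmid genes tested, 38 were higher and 6 lower. On the whole array, 20 lowered genes had all their probes at background on all mutant arrays, and the one outside this segment was SO_4416, named after its values were seen, with a bound under 1.

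**Figure D2:**
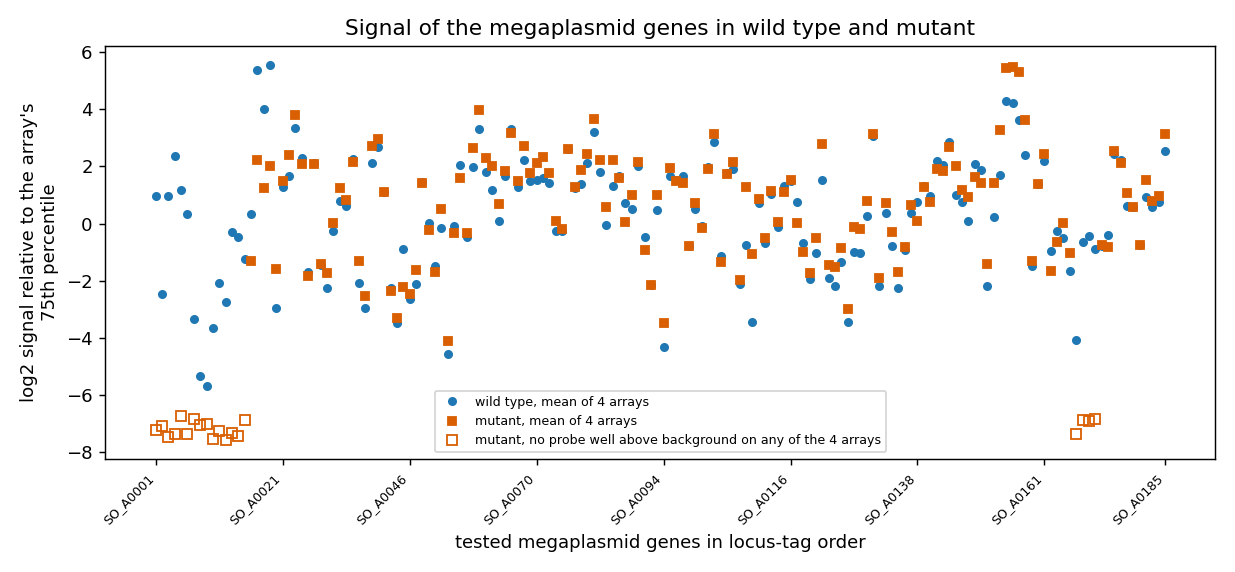
Mean log2 signal relative to the 75th percentile for each tested megaplasmid gene in locus-tag order, with circles for the wild type and squares for the mutant (4 arrays each). Open squares mark the 19 genes whose probes were not well above background on any mutant array, at SO_A0001 to SO_A0015 and SO_A0171 to SO_A0174.

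Genes of electron transport moved in both directions. In the list of conduits for extracellular electron transfer, 3 of 8 genes were lower and none higher. They were mtrB (SO_1776, log2 fold -0.76), mtrA (SO_1777, -0.82) and mtrC (SO_1778, 2-fold lower, SE 0.30 on the log2 scale), which together form the route across the outer membrane. Adjusted over the list alone, 4 were lower and 1 higher. Each of these calls was lost when single arrays were left out. The limma adjusted p of mtrB was 0.051 without wild-type replicate 3 and 0.0524 without mutant replicate 3. That of mtrA was 0.0543 without wild-type replicate 4 and 0.0562 without mutant replicate 3. That of mtrC was 0.0749, 0.0566 and 0.0956 without wild-type replicates 2, 3 and 4 and 0.0984 without mutant replicate 3. omcA had a log2 fold of -0.65 (limma adjusted p = 0.0663), and was called lower with normexp at the same percentile (0.0274), the brightest probe (0.0155), a replicate block (0.0387) or cyclic loess (0.0313) and without wild-type replicate 1 (0.0325) or mutant replicate 2 (0.0391). mtrF had a log2 fold of 0.04 and cymA, the quinol oxidase that feeds the route, one of 0.36. SO_1782 had one of 0.48 (limma adjusted p = 0.0742). It was called higher with normexp at the same percentile (0.00538) and without wild-type replicate 2 (0.0436) or mutant replicate 1 (0.0495). SO_1781 had a log2 fold of -0.07 and was called lower with the series matrix values (limma adjusted p = 0.0474). The list as a whole did not pass limma's camera test (adjusted p = 0.109), except without mutant replicate 2 and wild-type replicate 1 together (0.0485). None of the 11 genes of cytochrome c maturation, which attaches heme to these cytochromes, passed the test, over all genes or over the list alone, and their median log2 fold was 0.25. With the brightest probe of each gene, SO_0269 of this list was called higher (log2 fold 0.555, limma adjusted p = 0.0209). Among 43 c-type cytochrome genes, 9 were higher and 4 lower (12 and 5 adjusted over the list alone), and camera gave an adjusted p of 0.24. This balance moved with the scaling, to 20 higher and 3 lower with normexp at the same percentile, 5 and 6 with cyclic loess, 4 and 3 with the series matrix values and 3 and 3 with normexp and quantile normalization.

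Among 22 anaerobic reductase genes, 6 were higher and 5 lower (8 and 6 adjusted over the list alone). With normexp at the same percentile 9 were higher and 4 lower, and with normexp and quantile normalization 3 and 4. A run of 8 genes from napG (SO_0847) to SO_0854 rose, of which napG, napA and SO_0849 are in this list as genes of periplasmic nitrate reduction, and SO_0849 had a log2 fold of 1.57 (SE 0.30, limma adjusted p = 0.00421). The napG call was lost without any one of wild-type replicates 1, 3 or 4 or mutant replicates 1 to 3, with adjusted p from 0.0569 to 0.0909, and under normexp with quantile normalization (limma adjusted p = 0.0585). The SO_0854 call was lost with the brightest probe of each gene (limma adjusted p = 0.0535). Before the run, napH (SO_0846, 0.64) did not pass, and napB (SO_0845, 0.95) passed but lost its call without wild-type replicates 1, 3 or 4 or mutant replicates 1, 2 or 4 and under 5 other settings, with limma adjusted p from 0.0521 to 0.423. Of the dms genes for dimethyl sulfoxide reduction, SO_1428 to SO_1431 fell, with log2 folds of -1.33 for SO_1430 and -1.44 for SO_1428, whose limma adjusted p was 0.0531 without mutant replicate 3. SO_1427 (-0.63) and SO_4357 to SO_4360 (from -0.14 to 0.50) did not pass. The median of this list was 0.10, fry gave the direction up and limma's camera down (adjusted p = 0.751), and the median was -0.01 with the series matrix values and -0.02 with cyclic loess. Of 14 terminal oxidase genes, 3 were higher and 3 lower (3 and 6 adjusted over the list alone). coxB (SO_4606), of a cytochrome c oxidase, had a log2 fold of 1.06 and its neighbour SO_4608 one of 0.85, whose call was lost under normexp with quantile normalization (limma adjusted p = 0.0536). cydX (SO_3284), of the cytochrome bd oxidase, had one of -0.88 from 1 kept probe. Its value on mutant replicate 4 (3.139) was at the level of wild-type replicates 3 and 4 (3.135 and 3.139). The cydX call was lost without any one of wild-type replicates 2 to 4 or mutant replicates 1 to 3, with adjusted p from 0.0744 to 0.122, and under normexp with quantile normalization (limma adjusted p = 0.0627). This list did not pass (camera adjusted p of 0.0938 from limma), but did with normexp at the same percentile (0.0101), with array weights (0.0352) and without mutant replicate 4 (0.00258). Lower genes numbered 6 with normexp at the same percentile or with cyclic loess. In heme synthesis, hemF fell (log2 fold -1.17), hemB (SO_2587) rose (0.91) and hemA fell (-0.54), and the other 10 genes did not pass. The hemB call was lost without wild-type replicate 3 (limma adjusted p = 0.0709) or 4 (0.0608). The hemA call was lost without wild-type replicate 3 (0.0676) or 4 (0.0862) or mutant replicate 3 (0.0779) or 4 (0.0524), with a replicate block (0.0533) and with array weights (0.0542). The same 1 and 2 genes passed when adjusted over the list alone, and the median was 0.23 although limma's camera gave the direction down (adjusted p = 0.751).

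Of the genes of the envelope and heat stress responses, those past the test were higher in the mutant. In the envelope stress list, 7 of 9 genes rose, over all genes and adjusted over the list alone. rpoE (SO_1342), the sigma factor of that response, had a log2 fold of 1.22 (SE 0.19, limma adjusted p = 0.00137), and its regulators next to it, SO_1343 and SO_1344, had 1.36 and 1.04. For this list, camera gave an adjusted p of 0.00229 with the preset correlation and 0.658 with an estimated correlation. In the heat shock list, 6 of 14 genes rose (11 adjusted over the list alone), among them the chaperone genes SO_2277 (log2 fold 1.24), clpB (1.13) and dnaK (1.07). The dnaK call was lost without wild-type replicates 3 or 4 (limma adjusted p = 0.0722 and 0.0769) or without mutant replicates 1, 2 or 3 (0.0539, 0.0688 and 0.0817), and with the brightest probe (0.051). For heat shock, camera gave an adjusted p of 0.00489 with the preset correlation and 0.658 with an estimated correlation, normexp at the same percentile ended the list's call (0.066), and fry did not pass it (adjusted p = 0.0603 from limma). Of 9 sigma factor genes, 4 rose, over all genes and adjusted over the list alone, with rpoH, for heat shock, at 0.74 and SO_1986 at 0.87. With the series matrix values or cyclic loess 2 rose, and with normexp at the same percentile 6. The SO_1986 call was lost without any one of wild-type replicates 2 to 4 or mutant replicates 1 to 3, with adjusted p from 0.0718 to 0.108, and with the series matrix values (limma adjusted p = 0.054), cyclic loess (0.0577) or normexp and quantile normalization (0.0621). This list had a camera adjusted p of 0.0555. It passed with quantile normalization, alone (0.0418) or after normexp (0.0357), median centring (0.0487), the series matrix values (0.0318), cyclic loess (0.0319), array weights (0.0459), camera on ranks (0.0478) and limma's fry (adjusted p = 0.0219), and without wild-type replicate 1 (0.0465) or mutant replicate 4 (0.0273).

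Iron uptake, flagellar and prophage genes were mostly higher where they changed. In the iron acquisition list, 10 of 15 genes rose and none fell (12 adjusted over the list alone, and from 6 with normexp and quantile normalization to 11 with normexp at the same percentile over all genes), among them SO_3670 (log2 fold 1.85, SE 0.37, limma adjusted p = 0.00549), SO_3032 (1.72) and SO_3030 (1.63), of which the latter 2 belong to siderophore synthesis. For iron acquisition, camera gave an adjusted p of 0.000735 with the preset correlation and 0.658 with an estimated correlation. Among 4 iron storage genes, dpsA rose (1.25), over all genes and over the list alone. The median of that list was -0.14, but limma's camera gave the direction up (adjusted p = 0.869). Of 34 flagellar genes, 18 rose and none fell (23 adjusted over the list alone), led by fliE (2.82-fold), flgF (2.44-fold) and flgH (2.12-fold), parts of the basal body. Flagella had a camera adjusted p of 0.00102 with the preset correlation and 0.752 with an estimated correlation. Of the prophage genes, 40 of 75 rose and 4 fell in LambdaSo (49 and 5 adjusted over the list alone), 24 of 40 rose and none fell in MuSo1 (27 alone), and 28 of 53 rose and 7 fell in MuSo2 (31 and 11 alone). By scaling, the genes that rose numbered from 30 (series matrix values) to 62 (normexp at the same percentile) in LambdaSo and from 20 (cyclic loess) to 34 (normexp at the same percentile) in MuSo1 and in MuSo2, and those that fell in MuSo2 numbered 11 with cyclic loess and 2 with normexp at the same percentile. In LambdaSo, SO_3010 rose (log2 fold 1.33), SO_2984 rose (1.28) and SO_2943 fell (-1.54). In MuSo1, SO_0643 rose (1.62), SO_0646 rose (1.44) and SO_0676 rose (1.38). In MuSo2, SO_2656 rose (1.47), SO_2653 rose (1.33) and SO_2688 fell (-1.39). The camera adjusted p was 1.06e-06, 2.71e-06 and 0.0148 for the 3 lists with the preset correlation and 0.658, 0.658 and 0.754 with an estimated correlation. The MuSo2 call was lost with the brightest probe of each gene (adjusted p = 0.196 by camera in limma).

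**Figure D3:**
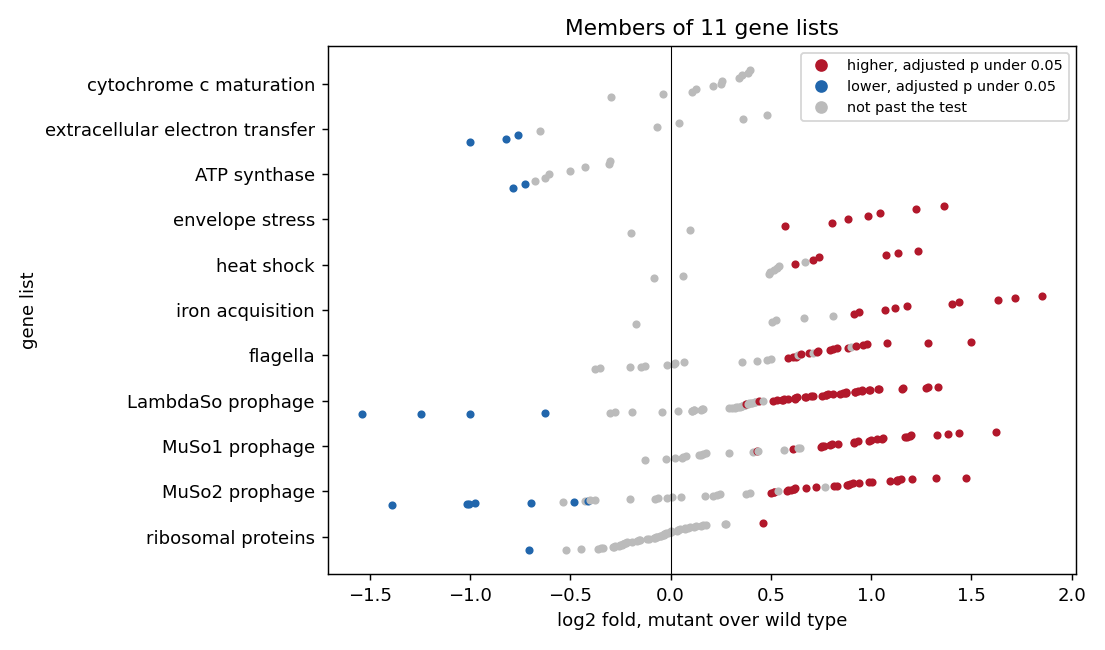
Log2 fold of mutant over wild type for the tested members of named gene lists, with 1 point per gene, red for higher, blue for lower and grey for genes not past the test. The points of envelope stress and iron acquisition that passed lie to the right of 0, and those of extracellular electron transfer and ATP synthase that passed lie to the left.

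The lists of growth, central metabolism and pili had medians below 0, from -0.61 for ATP synthase to -0.06 for ribosomal proteins. In the ATP synthase list, atpB (log2 fold -0.79) and atpE (-0.72) fell and the other 7 genes did not pass (6 lower adjusted over the list alone, and 5 lower over all genes with normexp at the same percentile or with cyclic loess). The atpE call was lost without any one of wild-type replicates 2 to 4 or mutant replicates 1 to 3, with adjusted p from 0.0623 to 0.105. ATP synthase had a camera adjusted p of 0.00171 with the preset correlation and 0.658 with an estimated correlation. Of 20 aminoacyl-tRNA ligase genes, 1 fell, gltX (-0.58), and none passed over the list alone. Its call was lost without wild-type replicates 3 or 4 (limma adjusted p = 0.0695 and 0.0631) or mutant replicate 3 (0.0557), and with the series matrix values (0.0598) or normexp and quantile normalization (0.0548). As a list, the ligases had a camera adjusted p of 0.0118 with the preset correlation, 0.658 with an estimated correlation, 0.0854 with the series matrix values and 0.0607 with normexp and quantile normalization. None of 19 genes of pyruvate, acetate and the tricarboxylic acid cycle passed, over all genes or over the list alone (4 were lower with normexp at the same percentile and 3 with cyclic loess), and the smallest p was that of acnB, with a log2 fold of -0.71 (limma adjusted p = 0.0504). acnB was called lower under 10 alternatives, among them the replicate block (limma adjusted p = 0.0208), array weights (0.0218), the brightest probe (0.0206) and the fit without mutant replicate 4 (0.0049). This list had a camera adjusted p of 0.0269 with the preset correlation, 0.754 with an estimated correlation, 0.0768 with quantile normalization, 0.116 with it after normexp, 0.0982 with the series matrix values, 0.0525 with cyclic loess and 0.055, 0.0556 and 0.27 without wild-type replicate 2 and mutant replicates 1 and 2. Among 54 ribosomal protein genes, rpmH fell (-0.71) and rpmI rose (0.46), and none passed over the list alone. With normexp at the same percentile 5 fell and none rose, and with the series matrix values none passed. The rpmH call was lost without wild-type replicate 3 (limma adjusted p = 0.0768) or mutant replicates 2 or 3 (0.0622 and 0.0653), and the rpmI call without wild-type replicates 1, 3 or 4 or mutant replicates 1, 2 or 4, with adjusted p from 0.0537 to 0.118. The rpmH call was also lost with the series matrix values (limma adjusted p = 0.082) and normexp with quantile normalization (0.0989). The rpmI call was also lost with both normexp settings, median centring, the series matrix values, cyclic loess and trend and robust variances, with limma adjusted p from 0.0583 to 0.101, and with the brightest probe (log2 fold 0.10, 0.644). Ribosomal proteins had a camera adjusted p of 0.0438 with the preset correlation, 0.808 with an estimated correlation, 0.275 with quantile normalization, 0.28 with it after normexp, 0.125 with the series matrix values, 0.0555 with array weights and 0.218, 0.066, 0.335 and 0.384 without wild-type replicates 2 and 3 and mutant replicates 2 and 3. Of 19 pilus genes, mshL fell (-0.49), and none passed over the list alone. With cyclic loess 4 fell and none rose, and with normexp at the same percentile 2 rose and 2 fell. The mshL call was lost without any one of wild-type replicates 1 to 4 or mutant replicates 2 or 3, with adjusted p from 0.0542 to 0.0907, and with normexp at the same percentile (limma adjusted p = 0.112) or with quantile normalization (0.0514) and with the series matrix values (0.0559). Pili had a camera adjusted p of 0.0456 with the preset correlation, 0.658 with an estimated correlation, 0.0636 with quantile normalization, 0.0928 with it after normexp, 0.0918 with the series matrix values, 0.199 with the brightest probe, 0.0515 with array weights, 0.0525 with cyclic loess and 0.055, 0.0748, 0.0909 and 0.051 without wild-type replicates 2 and 3 and mutant replicates 2 and 3.

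The remaining lists did not pass camera in the analysis as planned, although some did under other settings. In sulfate and cysteine synthesis, 3 of 11 genes rose (4 adjusted over the list alone), cysD, SO_3602 (log2 fold 1.27) and SO_3738 (1.25), and the camera adjusted p was 0.0699. With normexp at the same percentile 7 rose. This list passed with the series matrix values (0.0318), cyclic loess (0.0319), normexp and quantile normalization (0.0418) and the brightest probe (0.0375), and without mutant replicate 2 (limma's camera, adjusted p = 0.00113). In formate dehydrogenases and hydrogenases, 4 of 16 rose (5 higher and 1 lower over the list alone), among them fdxH (0.92), fdnG (0.77) and SO_4508 (0.54). The fdnG call was lost without wild-type replicates 3 or 4 (limma adjusted p = 0.0811 and 0.0675) or mutant replicate 3 (0.0599), and the SO_4508 call without wild-type replicates 2 or 3 (0.0508 and 0.0527). With normexp at the same percentile 8 rose. This list had a camera adjusted p of 0.234. Of 19 NADH dehydrogenase genes, SO_1020 (0.57) and nuoG (0.50) rose and none passed over the list alone (limma's camera, adjusted p = 0.339, and 0.0413 without mutant replicate 2). With normexp at the same percentile 8 rose. The SO_1020 call was lost without wild-type replicates 3 or 4 (0.0588 and 0.0516), and the nuoG call without wild-type replicates 2 to 4 or mutant replicates 1 or 3, with adjusted p from 0.058 to 0.112. The nuoG call was also lost with quantile normalization (limma adjusted p = 0.0562), median centring (0.0513), cyclic loess (0.0707), the series matrix values (log2 fold 0.27, 0.207) and normexp with quantile normalization (log2 fold 0.22, 0.186). Of 5 lactate oxidation genes, SO_1520 rose (0.64; 2 higher over the list alone; limma's camera, adjusted p = 0.24). Its call was lost without wild-type replicates 3 or 4 or mutant replicates 1, 2 or 3, with adjusted p from 0.0516 to 0.0887, and with array weights (limma adjusted p = 0.0592) or cyclic loess (0.0543). None of 8 genes of the mxd and bpf biofilm systems passed, over all genes or the list alone. Their median was -0.04 and reached 0.01 with normexp, camera gave the direction down (adjusted p = 0.765) and fry up, and mxdA had a log2 fold of 0.30 (limma adjusted p = 0.129). cheY, for chemotaxis, had a log2 fold of 0.41 (limma adjusted p = 0.0562) and passed with the series matrix values (0.0127), with normexp alone (0.01) or with quantile normalization (0.00668) and without mutant replicate 1 (0.0452), and dgcS, a diguanylate cyclase gene, rose (0.94, limma adjusted p = 0.0146). Over the 26 lists tested, 12 passed camera with the preset correlation, and none passed with an estimated correlation, adjusted or unadjusted. By fry 6 passed. Those of the 12 that did not were heat shock, flagella (limma adjusted p = 0.0622), MuSo2 (0.0653), pili (0.0993), the ligases (0.105), ATP synthase (0.112), the tricarboxylic acid cycle list (0.444) and ribosomal proteins (0.695). Of the 35 splits of the 8 arrays into 4 and 4, 6 gave as many shifted lists, so chance is not excluded for the number of lists.

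Changed genes lay side by side in the locus-tag order. Runs of at least 4 neighbouring genes called in the same direction numbered 47, of which 33 were higher and 14 lower, and held 293 genes. In 10000 permutations of the calls over the genes, the median was 3 runs and the highest 12, for a permutation p of 1e-04, the smallest these permutations can give. They treat genes as exchangeable, although neighbouring bacterial genes are often transcribed together. The p therefore shows only that calls cluster along the order. After the megaplasmid run, the longest were higher in the mutant and lay in prophages. They ran from SO_2653 to SO_2669 with 17 genes, from SO_3000 to SO_3012 with 13, from SO_0641 to SO_0652 with 12 and from SO_2979 to SO_2989 with 11. The lengths depend on the settings, since calls at their ends were lost. That of SO_2669 was lost without wild-type replicates 3 or 4 or mutant replicates 1 or 2, with quantile normalization, with cyclic loess and with the brightest probe of each gene, with limma adjusted p from 0.0573 to 0.585. That of SO_0641 was lost without any one of wild-type replicates 2 to 4 or mutant replicates 1 to 3, with the series matrix values, with normexp and quantile normalization and with the brightest probe, with limma adjusted p from 0.0636 to 0.202. That of SO_3000 was lost without wild-type replicates 3 or 4 or mutant replicate 3 and with the brightest probe, with limma adjusted p from 0.051 to 0.0723. Without mutant replicate 2 and wild-type replicate 1 together, the calls of SO_2669, SO_0641, SO_3000 and SO_2989 were lost. The limma adjusted p of SO_2989 was then 0.0653. A run of 8 genes from SO_4474 to SO_4481 was higher, with its largest change in SO_4476. The SO_4474 call was lost without wild-type replicates 2 or 4 or mutant replicates 1 to 3, with the series matrix values, with the brightest probe and under normexp with quantile normalization, with limma adjusted p from 0.0563 to 0.123. A run of 7 from brnQ (SO_0949) to SO_0955 was lower, with its largest change in dsbC (SO_0951), the periplasmic disulfide isomerase, which fell 15.8-fold (log2 fold -3.98, SE 0.17, limma adjusted p = 1.31e-08). The number of runs was 27 without wild-type replicate 3, 28 without mutant replicate 3 and 31 without wild-type replicate 4, 69 without mutant replicate 4 and 128 with normexp at the same percentile, and 12 at an adjusted p under 0.01.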

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

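Among the tests in this part, those on the separate parts of the megaplasmid segment were chosen only after the result was seen. The counts of splits for single lists and the prophage medians under other scalings were also chosen then.

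In 14 of 246 groups of 4 arrays, 1 array stood apart from the other 3 by Dixon's ratio of the gap to the range, where chance gives about 12. Of these 14, 7 concern mutant replicate 3. It stood above the others for coxB (SO_4606, ratio 0.917, -0.57 against a mean of -1.50), SO_4608 (0.942), fdxH (SO_0102, 0.936), fdnG (SO_0101, 0.834), SO_3102 (0.869), SO_0643 (0.843, 0.17 against -0.71) and SO_0652 (0.845). Mutant replicate 2 stood above for ccmE (SO_0259, 0.923) and SO_3090 (0.948, 1.16 against 0.54). In the wild type, replicate 2 stood above for SO_1977 (0.832) and replicate 1 for SO_1689 (0.949, -1.15 against -1.88). Wild-type replicate 4 stood above for SO_4508 (0.898) and below for cheY (SO_3209, 0.841), and replicate 3 stood above for rpmH (SO_0007, 0.858).

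The splits of the 8 arrays into 4 and 4 number 35, the real one included. The real split gave 1115 changed genes and the highest other 1, so 1 split in 35 reached the real value, the fewest that can. This argues against chance for the count, although the real split is also that of slide row. The same holds for genes changed at least 2-fold, 300 against 1 in the highest other and again 1 split as large. Runs numbered 47 against 0 in the highest other, also 1 split, but with at most 1 gene called no run could arise there, so this says nothing beyond the count of genes. For shifted gene lists, 6 splits gave as many as the real 12 and the highest gave 17, so chance is not excluded. For single lists, as small a camera p came from 1 split for envelope stress, 5 for LambdaSo, 6 for MuSo1, 8 for iron acquisition, 8 for heat shock, 9 for pili, 11 for flagella, 12 for ATP synthase, 13 for MuSo2, 13 for the ligases, 20 for the tricarboxylic acid cycle list and 22 for ribosomal proteins.

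A first pattern is the megaplasmid segment that was low in the mutant. Of 13172 probes in the segment's wild-type range, 3.49% were missed on at least 1 mutant array, under the bound set beforehand. That range is wide, and of 2327 probes matched more closely on level 9.67% were missed, which is over that bound and decides nothing by it. Only 0.859% of the matched probes were missed on all 4 mutant arrays, while all 51 probes of SO_A0001 to SO_A0015 and SO_A0171 to SO_A0174 were. For these genes that argues against dimmer arrays, or an effect of slide row on all probes of such levels. The test of loss set beforehand took the whole segment. In it 19% of 63 probes were well above background on all 4 mutant arrays, over the bound of 10% set for loss. Those probes are of SO_A0016 to SO_A0019. For SO_A0001 to SO_A0015 and SO_A0171 to SO_A0174, 0% of 51 probes were so, as loss of this part from the mutant's plasmid would give. This part was set apart after the values were seen, so its 0% was known and is no test of loss. Of these genes, the 16 placed in the reference order lay side by side there, with 0 other tested genes between them. Lower transcription with the genes present stays open, because an RNA at background does not show whether its gene is there. Of 55 probes of chromosomal genes lowered at least 16-fold, the deleted gene included, 7.27% were at background on all mutant arrays. That share cannot decide the question, because these chromosomal genes were not matched to the segment on wild-type level. A brighter gene can fall as far and stay above background. Whether SO_A0016 to SO_A0019 were lost too is left open. Their probes may read 4 genes of equal length not on the array, SO_A0167 to SO_A0170, which the bound of 10% did not allow for. The median log2 fold of SO_A0016 to SO_A0019, -2.954, is lower than loss of 1 of 2 equally transcribed copies gives.

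A second pattern is that more genes were higher than lower in the mutant, whose arrays were dimmer. Genes called higher from 6 arrays kept 91.3% of their median log2 fold in the held-out pair of equal brightness, wild-type replicate 4 and mutant replicate 1 (0.93 against 0.85 over 364 genes), so dimness as the cause of these rises is argued against. In that pair 97% of them were higher, and 90.1% of the 212 genes called lower were lower. The pair is a single array of each strain. Its brightness was equal in the 75th percentile of signal (1216 and 1215), while the median signal of the E1A spike-in controls was 152.2 on wild-type replicate 4 and 208.5 on mutant replicate 1. All genes together had a median of 0.134 in it against 0.078 over the 6 arrays. Only the 364 genes called higher from 6 arrays were tried, not all 799 higher genes. The share of calls that are higher still depends on the scaling, from 53.2% to 85.9%. Slide row and strain cannot be told apart, and that keeps a technical origin open for this pattern and for the prophage genes. If the megaplasmid segment was lost, effects of that loss on other genes cannot be told apart from those of the SO_3096 deletion.

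A further pattern is that prophage genes were more often higher than lower, 92 of 168 against 11, with a median log2 fold of 0.57. Under other scalings the median went from 0.31 with normexp and quantile normalization to 0.74 with normexp at the 75th percentile, and the higher genes from 72 with cyclic loess to 130 with normexp at the 75th percentile. A rise of weak signals on dimmer arrays is argued against, since 10000 lists matched on wild-type level had a median of 0.141 and reached from -0.003 to 0.286. The prophage median lay above all of them (percentile 100), also under each of 6 other scalings of the same arrays. These lists hold genes drawn at random, while prophage genes vary together (estimated correlation 0.172 for LambdaSo, 0.403 for MuSo1 and 0.3 for MuSo2). Their spread is therefore too narrow to weigh chance. Dimness alone is argued against by the pair of equal brightness, a single array of each strain, which showed 135% of the median over the other 6 arrays. The prophage medians were 0.695 and 0.516, and those of all genes 0.134 and 0.078. The deletion may bear on these genes, which was not tested apart from slide row or from a loss of the megaplasmid segment. Chance is not excluded for the single prophage lists by the splits.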

How the results depend on the processing

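The alternatives added after the data were seen are both normexp settings, cyclic loess and the fit without mutant replicate 2 and wild-type replicate 1. SO_3096 was called lower under all settings run, with a log2 fold of -4.99 from the 1 probe above background on all arrays. No call of a named gene or list was reversed, although some log2 folds and medians of genes and lists not past the test changed sign. Normexp at the 75th percentile gave 2004 changed genes, 1722 of them higher, and 128 runs, and raised the median log2 fold of all genes by 0.16, from 0.08 to 0.24. Normexp with quantile normalization gave 187 genes changed at least 2-fold. Cyclic loess gave 505 lower genes and took that median to -0.03, a shift of -0.10. For these settings the cause was not tested. The fit without mutant replicate 2 and wild-type replicate 1, with fewer samples, gave 31 runs. It lost the calls of 17 of the 120 named genes, among them cydX (limma adjusted p = 0.0876), napG (0.12) and SO_1520 (0.0906). Most of these losses are not repeated beside the genes above. A threshold of 0.01 gave 440 changed genes, 280 higher and 160 lower, and 12 runs. Runs of at least 3 genes numbered 79. Estimated correlations called 0 lists and fry 6.

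Leaving out each array in turn gave 694 to 1429 changed genes, 477 to 1034 higher, 217 to 395 lower, 240 to 378 changed at least 2-fold, 27 to 69 runs and 9 to 14 lists. The lowest count came without mutant replicate 3, and the counts without wild-type replicates 3 and 4 were 719 and 742. Of 120 named genes, up to 22 calls were lost in this way, the most without wild-type replicate 3.

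With a replicate block, 1178 genes changed (848 higher, 330 lower), 1044 of them shared with the fit without it. Deviations of arrays with the same number correlated across genes at r of 0.249, 0.131, -0.142 and 0.236, and only the arrays numbered 4 correlated best with their own number, so the numbers were not taken as pairs. Normexp on mean signals was not run, since the files used here hold median signals, and a slide or scan block was not run. Signal over background limits weak genes on the mutant arrays, where between 95.43% and 98.7% of probes were well above it.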

Other observations

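The test of thiol redox genes in this part was chosen only after the result was seen, as were all genes named here.

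The phage shock genes, a response to damage of the inner membrane, lay in a run of 6 higher genes from SO_1807 to SO_1812. pspA (SO_1807) rose 3.05-fold (log2 fold 1.61, SE 0.24, limma adjusted p = 0.00106, n = 4 each) and was higher on 4 of 4 mutant arrays than on any wild-type array, and pspB (SO_1808) rose 2.62-fold. A run of 7 lower genes from murA (SO_3948, log2 fold -0.97) to mlaF (SO_3954, log2 fold -0.77) holds mlaD, mlaE and mlaF, of a system for phospholipid traffic between the membranes. A run of 5 higher genes held ilvA, ilvD, ilvM and ilvG of branched-chain amino acid synthesis, with ilvG (SO_4347) at a log2 fold of 1.13. On the megaplasmid, SO_A0153 to SO_A0158 were higher as a run of 6, and SO_A0157 rose 3.17-fold.

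Several genes of thiol and methionine sulfoxide redox chemistry stood among the strongly lowered genes. msrQ (SO_2043) fell 52-fold (log2 fold -5.70, SE 0.20, limma adjusted p = 1.73e-09, n = 4 each) and msrP (SO_2042), which repairs oxidised methionine in the periplasm, fell 40-fold. gorA (SO_4702), glutathione reductase, fell 8.27-fold, and gshA (SO_3559), of glutathione synthesis, fell 7.83-fold. With dsbC, 5 of 11 genes with symbols of this kind were lower, 45.5% against 6.29% of 1208 other genes with a symbol (Fisher's exact test, two-sided, p = 0.000386). trxB (log2 fold 0.93) and dsbB (0.98) were higher. The symbols were picked after the lowered genes were seen, so this test decides nothing.

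Other strongly lowered genes were SO_1837 (log2 fold -6.02, SE 0.14), SO_1380 (-5.51), next to SO_1381, SO_2588 (-5.46), SO_2710 (-4.63), SO_0696 (-4.09) and cutA (SO_0697, -4.04).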
